A study of Cereibacter sphaeroides 2.4.1 with 3 samples.

How the data were processed

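The RNA came from Rhodobacter sphaeroides 2.4.1 (also listed as Cereibacter sphaeroides), a photosynthetic bacterium, carrying either a plasmid with the small RNA gene sorX (pRKSorX144) or the empty plasmid pRK415. Per the labels' protocols, cultures grew under aerobic conditions to an OD660 of 0.4 and were exposed for 7 min to 0.2 µM methylene blue under light of 800 W per square metre. The dye transfers light energy to oxygen and so makes singlet oxygen. Total RNA was extracted with hot phenol and labelled directly with a platinum-linked dye kit. On each of 3 2-colour Agilent arrays, RNA of the SorX plasmid carried Cy3 (green) and RNA of the empty vector Cy5 (red), per the labels. There was no dye-swapped array, so an effect of the dyes on single features cannot be told apart from the effect of the plasmid.

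Per the labels, each array held pools of 3 cultures. Array 1 held the pool of cultures 1 to 3, array 2 the pool of cultures 4 to 6, and array 3 the pool of cultures 1 to 3 again as a technical array. The biological replicates were therefore 2 pools. The replicate test and the main tests of the feature classes took values from these 2 pools. The standard error of the replicate test was a spread pooled over all features, so its p-values do not measure the spread between pools. The file headers put arrays 1 and 2 on 1 slide, read in the same scan (slide 1), and array 3 on another slide, scanned in an earlier year (slide 2). Whether RNA of pool 1 was stored between these arrays is not given in the sources used here.

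The deposited scanner files held the median intensity of each spot and of the surrounding background in both colours, made with Feature Extraction 10.7.3.1, per the file headers. They also held a processed intensity, with background subtracted and dyes normalized by the scanner software, per the file headers. The log10 ratio column of the deposited files (red over green) was not used for a result. The design had named mean spot intensities, but the files used here held medians, so medians were used. The authors' deposited table of log2 values gave no scale, direction or steps. The submitters' processing notes name limma, with no version. Set against the scanner signals, this table matched log2 green over red after loess without background subtraction, with the spots of a probe averaged. The correlation across probes was 0.9995 for array 1, 0.9992 for array 2 and 0.9992 for array 3, and the slopes were 1.00 on all 3. The medians of its columns were -0.0025, -0.0013 and 0.0036. Its row identifiers counted the non-control spots in file order. Scale, centring and direction were settled by this match.

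Signals were corrected with normexp (offset 50), normalized by loess within each array with control spots and outlier spots at weight 0, and expressed as the log2 ratio of SorX plasmid over empty vector (limma 3.58.1, R 4.3.3). Spots of a probe were averaged. A probe was kept when at least 1 channel was well above background on every array, which left 12873 of 13218 probes. Probes of a feature were averaged, giving 4515 of 4516 features. When each probe was tested alone, 682 features had probes past the threshold in opposite directions. The 2 arrays of pool 1 were averaged before the fit. Pool 1 therefore joins both slides while pool 2 holds slide 1 only. The SD over the 2 pools, printed after ±, mixes slide with pool and does not measure the spread between cultures. The mean of the 2 replicates was tested against 0 with lmFit and eBayes and adjusted by Benjamini-Hochberg at 0.05 (the replicate test). A test with the 2 slides as replicates, the arrays of slide 1 averaged, was added after the data were seen (the slide test). It measures the spread between slides, of which both hold pool 1, and not the spread between cultures. The adjusted p printed for single features come from the slide test unless stated otherwise. The ratios printed beside them are means of the 2 pools, which give slide 1 more weight. The slide test uses the mean of the 2 slides, so ratio and adjusted p belong to different means. The numbers of features past a threshold of 2-fold (log2 of 1) in both replicates were also counted. Every test below is two-sided, apart from the permutations of the feature numbers, which were set against their highest values only.

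Of the 4515 features, 4371 had 9-digit numbers for names. Neither the files used here nor the reference table (RefSeq annotation of assembly ASM332471v1) pairs these numbers with genes, and 0 of them matched it. The 19 gene lists fixed before the data were examined therefore could not be tested. The 144 other features had names that describe an intergenic region and strand, an antisense RNA, or an end of a gene. These classes were set after the names were seen and were tested in place of the lists with camera (preset correlation 0.01), camera with an estimated correlation, and fry. Camera at the preset correlation sets a class against the other features, so its p-value does not measure the spread between pools. Coordinates in feature names are the authors', on a genome build not given in the sources used here. Of 73 region names with coordinates, 53 matched a gap of exactly the same length between neighbouring genes of ASM332471v1, shifted by at most 109 bases. Gene neighbours were taken from these matches. Both counts take 0680a, 0680b and 0680c apart, though these share the same coordinates.

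The named features are, by the rule set before the data were examined, the SorX region and the 10 highest and 10 lowest mean log2 ratios among features past the replicate test with the same sign on all 3 arrays. The rule also took the polyamine transport and RpoE lists and up to 4 members of each other list, which had no names to match. Of the numbered features, 2 higher and 2 lower are printed. Further named features, chosen after their values were seen, are those past both tests with a log2 ratio of at least 0.5 in size and the same sign on all 3 arrays.

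Per array, between 95.0% and 99.8% of non-control spots were well above background in green and between 96.8% and 98.0% in red. No non-control spot was saturated or carried an outlier flag. The number of arrays limits the precision. In ratios simulated for all 4515 features with the measured spread within and between slides, the replicate test called 25.5% of 4315 unchanged features and the slide test 0.139%. With the same spread placed between replicates instead of slides, the result turned round: the replicate test called 0.209% and the slide test 25.5%. These shares follow from where the simulation put the spread, so they do not show which test suits the data. With the spread between slides, the slide test found 86.6% of 67 features changed by a log2 of 0.5, 100% of 67 changed by 1 and 100% of 66 changed by 2. Alternatives covered the background correction, dye normalization, filter, treatment of the technical array, probe averaging, variance prior, the authors' table and each replicate left out. Median centring, run in place of loess, takes a constant off each array and so keeps any trend of the ratio with brightness, which loess removes.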

Results

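Transcript levels were measured after 7 min of singlet oxygen stress in R. sphaeroides carrying the SorX plasmid and in cells with the empty vector, side by side on 3 2-colour arrays. SorX is a small regulatory RNA made under oxidative stress, and the comparison asks which transcripts differ when its gene is present on a plasmid. There was 1 comparison, with 2 biological replicates (each a pool of 3 cultures) and a technical array of pool 1. All 3 arrays carried the same dyes, so each ratio below holds any dye effect of its feature. The median spot brightness was 4422, 3802.5 and 6833.5 in green and 5353.5, 4801.75 and 5515 in red on arrays 1, 2 and 3. Negative-control spots had a median of 1404, 1272 and 965 in green.

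The SorX region was higher with the SorX plasmid on every array. The feature IGR_2461_2598245_2598592_sense covers the intergenic region numbered 2461, the number under which SorX was catalogued (RSs2461), and no feature was named SorX itself. Its mean log2 ratio was 2.00 ± 0.12 (SD, n = 2 pools), a 3.99-fold difference. It measured 1.89 on array 1, 1.91 on array 2 and 2.28 on array 3. The adjusted p (limma) was 3.1e-05 in the slide test. Its 2 probes gave similar values, 1.86 and 1.92 on array 1, 1.85 and 1.97 on array 2, and 2.11 and 2.45 on array 3. With median centring in place of loess the value was 1.14.

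Besides SorX, 4 of the 10 highest features carry the numbers of the small RNAs SorY and CcsR. They were matched by catalogue number alone, after their values were seen, and small RNA regions were not tested as a group. Not all intergenic regions rose: IGR_0682_694011_694910_sense had a mean of -0.35 ± 0.18 (SD, n = 2 pools), with -0.45 and -0.48 on slide 1 and 0.004 on slide 2. The slides disagreed on IGR_0019_sense, at -0.09 and -0.08 on slide 1 and 0.40 on slide 2, with a mean of 0.04 ± 0.17. It carries the number of the small RNA Pos19, but its name gives no coordinates, so this match is uncertain. IGR_1543_1632533_1632899_sense carries the number of the small RNA SorY (RSs1543) and had no match of equal length in assembly ASM332471v1. It rose by 2.05 ± 0.17 (SD, n = 2 pools) on the log2 scale, or 4.14-fold, and by 1.15 with median centring. Region 0680 carries the number of the CcsR RNAs, a family of related small RNAs made under stress. IGR_0680c_691544_692463_antisense rose by 2.14 ± 0.24, IGR_0680b_691544_692463_antisense by 2.10 ± 0.21 and IGR_0680a_691544_692463_antisense by 1.66 ± 0.12 (SD, n = 2 pools). With median centring the 3 values were 1.91, 1.93 and 1.25, against 1.14 for SorX. With the scanner software's processed signals IGR_1543_1632533_1632899_sense stood at 2.47 and SorX at 1.89. The CcsR probes may also bind each other's RNA, which was not examined, so the 3 values cannot be taken as separate measurements. All 4 features passed the slide test (limma), with adjusted p of 3.1e-05 for IGR_1543_1632533_1632899_sense and 4.27e-05 for IGR_0680c_691544_692463_antisense. No difference between SorX and these regions was tested.

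Other named features with the highest ratios were RSsh1, at 1.15 ± 0.08, and 3'RSP3594, named for an end of gene RSP3594, at 1.14 ± 0.01 (SD, n = 2 pools). RSsh1 was 2.21-fold and 3'RSP3594 2.20-fold higher, both with adjusted p 0.000194 in the slide test (limma). IGR_0939_974899_974972_sense rose by 1.10 ± 0.17 and IGR_0827_858004_858191_sense by 1.07 ± 0.11. The latter lies next to rlmB in assembly ASM332471v1, a gene that codes for an rRNA methyltransferase. IGR_0293_antisense rose by 0.83 and IGR_0148_sense by 0.73. With median centring 3'RSP3594 stood at 0.67, IGR_0827_858004_858191_sense at 0.66 and IGR_0293_antisense at 0.29. With the scanner software's processed signals IGR_0293_antisense stood at 1.28.

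The named feature with the lowest ratio was IGR_0552_sense, at -1.43 ± 0.22 (SD, n = 2 pools). It was 2.69-fold lower with the SorX plasmid. Its mean of the 2 slides was -1.28, with an adjusted p of 0.000786 in the slide test (limma). IGR_0552_sense stood at -1.56 and -1.58 on slide 1 and at -0.98 on slide 2, and at -2.39 with median centring. IGR_2750_2896542_2896820_sense, next to dxs, stood at -0.96 ± 0.06. The gene dxs codes for the enzyme of the first step of isoprenoid synthesis. IGR_2378_2509141_2509377_antisense, next to the polyphosphate kinase gene ppk2, stood at -0.79 ± 0.03. IGR_0272_sense stood at -0.52 and IGR_0545_antisense at -0.50. The ratio of IGR_0545_antisense was -0.81 with median centring, and with pool 1 given by array 3 alone IGR_0272_sense had an adjusted p of 0.0528.

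**Figure D1:**
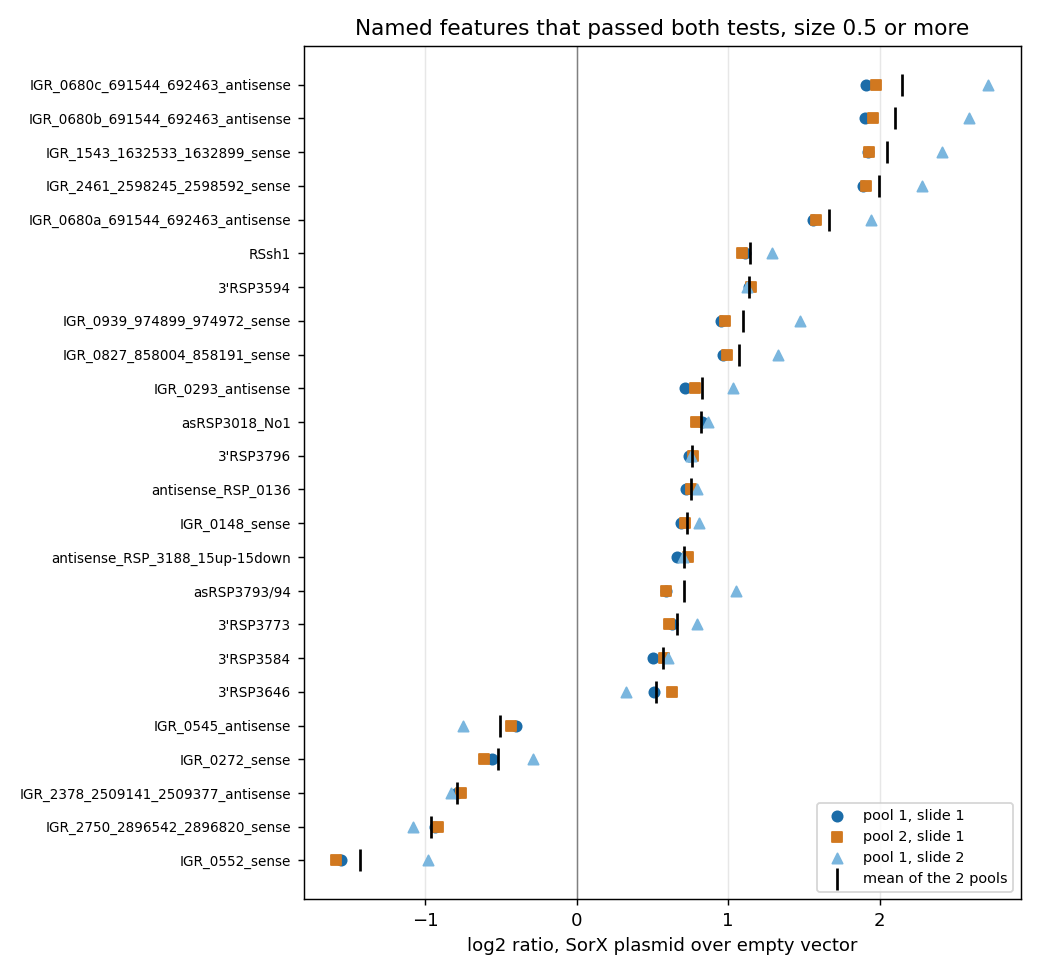
Log2 ratio of SorX plasmid over empty vector (x axis) for the 24 named features past both tests with a size of at least 0.5; symbols are single arrays and the bar is the mean of the 2 pools. Of these features 19 lie above 0 and 5 below, and for 21 of the 24 arrays 1 and 2, of different pools on slide 1, lie closer together than either does to array 3. The exceptions are 3'RSP3796, antisense_RSP_3188_15up-15down and 3'RSP3584.

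Features named for RNA antisense to a gene had mostly higher ratios. Of 23 such features, 13 rose, 2 fell and 8 did not pass the replicate test. In the slide test 7 rose and 0 fell. Their median log2 ratio was 0.16, against 0.01 for the numbered features. In the mean of the 2 pools those named asRSP all stood above 0, from 0.16 (asRSP3619) to 0.82 (asRSP3018_No1). The slides disagreed on asRSP3619, counted among the 13, at 0.40 and 0.38 on slide 1 and -0.51 on slide 2. Its mean of the 2 slides was -0.06. They also disagreed on antisense_RSP_3837, counted among the 2 that fell, at -0.24 and -0.25 on slide 1 and 0.02 on slide 2. Those named antisense_RSP lay on both sides of 0, from -0.29 (antisense_RSP_1198) to 0.76 (antisense_RSP_0136). By their probe names these 2 forms belong to different probe design sets, so a rise of the class cannot be told apart from a difference between the sets. Examples are asRSP3018_No1 at 0.82 ± 0.04, antisense_RSP_0136 at 0.76 ± 0.001 and antisense_RSP_3188_15up-15down at 0.71 ± 0.04 (SD, n = 2 pools). On arrays 1, 2 and 3 antisense_RSP_0136 stood at 0.72, 0.76 and 0.79. The feature asRSP3793/94 stood at 0.71, but at -0.08 with median centring. The class passed camera with the preset correlation (adjusted p = 0.00396 over 4 classes, limma). The adjusted p was 0.339 with an estimated correlation, 0.132 with array 3 left out and 0.225 with median centring. In fry (limma) it was 0.0445 with the pools as replicates and 0.111 with the slides as replicates. With median centring the class median was 0.04, with 8 rising and 3 falling. The count adjusted over the list alone was 15.

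Features named for the 3' or 5' end of a gene also had mostly higher ratios. Of 11 such features, 7 rose, 1 fell and 3 did not pass the replicate test, and in the slide test 6 rose and 0 fell. By their probe names they share the design set of the asRSP features, so class and set cannot be told apart. Besides 3'RSP3594, 3'RSP3796 rose by 0.76 ± 0.01 and 3'RSP3773 by 0.66 ± 0.07 (SD, n = 2 pools). The mean of 3'RSP3646 was 0.53 ± 0.15, but its 2 probes went opposite ways, at -0.20 and 1.23 on array 1, -0.21 and 1.47 on array 2, and -0.36 and 1.01 on array 3. The feature 3'RSP3584 stood at 0.57, but at -0.004 with median centring and at 1.01 with the scanner software's processed signals. The class median was 0.30 and the adjusted p was 0.000455 with camera at the preset correlation (limma). It was 0.339 with an estimated correlation and 0.205 with array 3 left out. In fry (limma) it was 0.0445 with the pools as replicates and 0.159 with the slides as replicates. The class median was 0.16 with median centring (adjusted p = 0.0306 in camera, limma, and adjusted p = 0.337 with an estimated correlation) and 0.54 with the scanner software's processed signals. The count adjusted over the list alone was 8.

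Features of intergenic regions went both ways. On the sense strand, 17 of 59 rose and 20 fell in the replicate test, with a median of 0.03 and an adjusted p of 0.327 (camera, limma). On the antisense strand, 14 of 48 rose and 13 fell, with a median of 0.01 and an adjusted p of 0.0675. With an estimated correlation the adjusted p was 0.641 and 0.339. In fry (limma) it was 0.283 and 0.0938 with the pools as replicates, and 0.347 and 0.259 with the slides as replicates. In the slide test, 12 rose and 5 fell on the sense strand and 9 rose and 2 fell on the antisense strand. With median centring 9 rose and 36 fell on the sense strand and 10 rose and 27 fell on the antisense strand. The medians were then -0.26 and -0.21, with adjusted p of 1.9e-05 and 0.0306 in camera at the preset correlation (limma). With an estimated correlation the adjusted p was 0.337 for both. The counts adjusted over the list alone were 37 and 27.

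Across all 4515 features, 624 passed the slide test, 383 higher and 241 lower with the SorX plasmid. The replicate test passed 2554 features, 1354 higher and 1200 lower, and took in all 624 of the slide test. Its standard error was 0.067 for every feature, since the fitted prior outweighed the single degree of freedom of each feature. With array 3 left out 3908 features passed, and with pool 1 given by array 3 alone 377 passed. At least 2-fold differences of the same sign in both replicates were seen for 18 features, 11 higher and 7 lower. The numbered features made up 10 of these and the named features 8. Replicate 1 averages both slides, and some of the lower features missed 2-fold on array 3, such as 640709959 at -0.62 and IGR_0552_sense at -0.98. All of the higher features passed it there. The split between higher and lower features depended on the setting. It stayed mostly higher with no background subtraction (10 higher and 5 lower) and with probes above background in both channels (13 and 7). It was 17 higher and 14 lower with the scanner software's processed signals. Other settings turned it to mostly lower, of which those with array 3 or replicate 1 left out rest on slide 1 alone. Leaving out array 3 gave 12 higher and 29 lower (41 in all), leaving out replicate 1 gave 16 higher and 31 lower (47), and median centring gave 11 higher and 70 lower (81).

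Some numbered features reached ratios above 1 or below -1. Feature 640072129 stood at 1.74 ± 0.11 and feature 640071767 at 1.62 ± 0.003 (SD, n = 2 pools), with adjusted p of 3.1e-05 for both in the slide test (limma). On arrays 1, 2 and 3 feature 640071767 stood at 1.52, 1.62 and 1.71. Feature 640070755 stood at -1.61 ± 0.30 and feature 640709959 at -1.42 ± 0.40. The means of the 2 slides were smaller in size, at -1.42 for 640070755 and -1.15 for 640709959. These had adjusted p of 0.000981 and 0.00857 in the slide test (limma). On slide 1 feature 640709959 stood at -1.66 and -1.71, and on slide 2 at -0.62. Feature 640072129 stood at 1.10 on the authors' table, at 1.11 with no background subtraction and at 1.13 with plain subtraction. Feature 640070755 stood at -1.08 with no background subtraction, and with median centring feature 640709959 stood at -2.50. All 10 highest and all 10 lowest features of the naming rule passed the slide test. They were chosen for large ratios of the same sign on the same 3 arrays, so this gives no separate support. Of the 10 highest, 6 were named features, and of the 10 lowest, 1.

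Agreement between arrays followed the slide. Across the 4515 features, log2 ratios correlated at r = 0.989 (Spearman 0.986) between arrays 1 and 2, which held different pools on slide 1. The correlation was 0.688 (Spearman 0.650) between arrays 1 and 3, which held the same pool on different slides, and 0.678 between arrays 2 and 3. Features are not independent replicates. The SD of the difference was 0.0496 within slide 1 and 0.235 between the arrays of pool 1. The sign was shared by 95.4% of features in the first pair and 74.0% in the second. Between the arrays of slide 1 the same spot had an SD of 0.0694, while 2 spots of a probe within array 1 had an SD of 0.152. No pool was hybridised 2 times on 1 slide, so whether the pools differed by more than technical noise could not be tested. The slide test counts the arrays of slide 1 once.

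**Figure D2:**
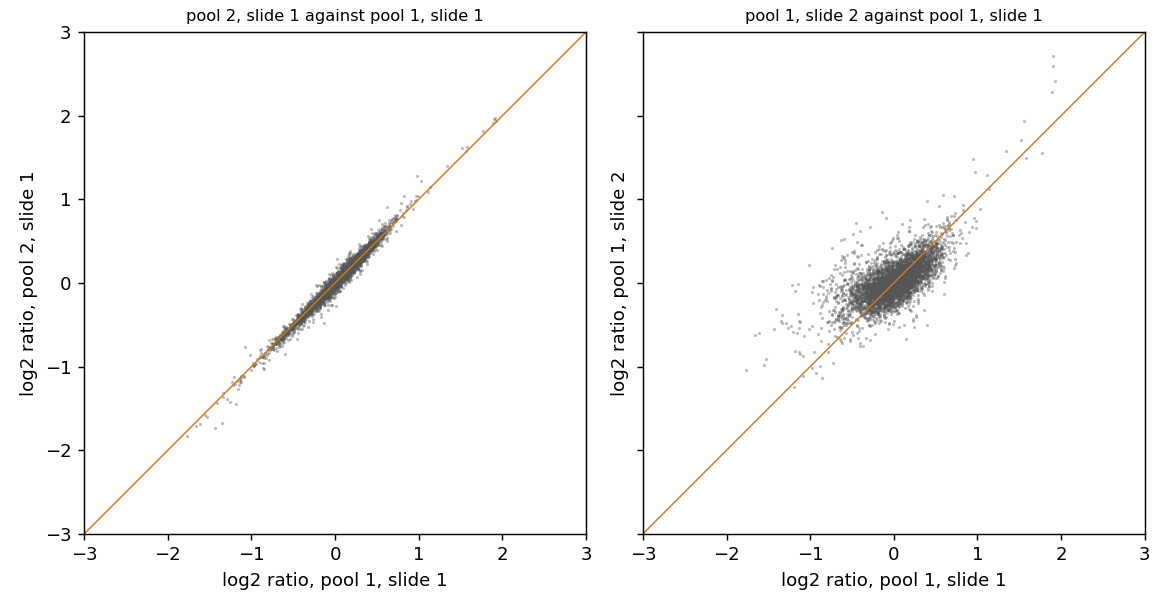
Log2 ratio of SorX plasmid over empty vector on array 1 (pool 1, slide 1; x axes) against array 2 (pool 2, slide 1; left) and array 3 (pool 1, slide 2; right), with 1 point for each of 4515 features and the line of equal values. Points lie closer to the line on the left (r = 0.989) than on the right (r = 0.688).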

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

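The tests of slide and scan, of shared spot effects and of dye effects were chosen after the result was seen. The E1A control spots, which the comparison does not use, were brighter than the negative-control spots in both colours. The ratio of their medians was at least 1.37 in green and at least 1.44 in red on each of the 3 arrays.

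The 2 arrays of pool 1 differed more than the arrays of the 2 pools on slide 1. The difference between 2 spots of 1 probe, which no difference in RNA can make, correlated at 0.851 between the arrays of slide 1 and at 0.181 between the arrays of pool 1. Effects on single spots therefore followed the slide and scan. The spot difference cancels whatever the 2 spots of a probe share. It therefore cannot show whether differences of whole probes between the arrays of pool 1 came from slide and scan. Dim features do not account for the larger difference within pool 1, since r between its arrays was 0.655 in the brighter features (the highest of 3 equal parts). A wrong pool on array 3 stays open: the partial correlation of array 3 with array 1 minus array 2 was 0.124, above the 0 first set as the limit, but spot differences (0.0558) and unequal noise (up to 0.0811) together allow 0.137.

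With slide 1 alone, 3908 features passed the test. Spots side by side of unrelated features correlated at 0.0924 ± 0.0085 (SE) on array 1, too near the limit of 0.1 set beforehand to decide on an effect of the layout. Of these features 34.8% lay within 2 SD of the spot effect that the arrays of slide 1 share (SD 0.147), so such effects may account for part of the count. Dye effects of single features cannot be told apart from the plasmid, as every array carried the same dyes. An effect of the plasmid on many transcripts stays open too, as untested.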

How the results depend on the processing

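SorX kept its direction under every alternative run, with log2 ratios between 1.14 (median centring) and 2.09 (pool 1 by array 3 alone). Without 1 replicate each, it was 1.91 to 2.08. The count of features past the test was 3908 with array 3 left out, 3911 with each probe tested alone, 624 with the slides as replicates and 377 with pool 1 by array 3 alone, against 2554. With each probe tested alone, a feature counted when any of its probes passed, so 3911 and 2554 follow different counting rules. The other 13 alternatives gave counts within 1.5 times. Among them, quantile scaling of the brightness after loess leaves the ratios as they are, so its count of 2554 was fixed in advance. The size rule gave 31 features with the scanner software's processed signals, 81 with median centring, 41 with array 3 left out and 84 with each probe alone, against 18. Without 1 replicate each, it gave 21 to 47. For settings other than median centring the cause was not tested. With median centring, asRSP3793/94 stood at -0.075 and 3'RSP3584 at -0.0035. The medians of the intergenic classes, 0.03 (sense) and 0.01 (antisense), were -0.26 and -0.21 with median centring. That setting differs from loess only in keeping the trend of the ratio with brightness. The dim 3'RSP3796 (mean log2 brightness 11.4) moved little, from 0.76 to 0.78. The bright SorX feature (17.1) moved from 2.00 to 1.14 and IGR_0552_sense (17.5) from -1.43 to -2.39. Whether the trend holds any effect of the plasmid was not tested. Of the 24 plotted and 4 numbered features, the only ones run under each alternative, all but asRSP3793/94 and 3'RSP3584 kept their sign. IGR_0272_sense lost its call with pool 1 by array 3 alone (-0.45). Slides as replicates, pool 1 by array 3 alone, the negative-control level as background and the feature classes were added after the data were seen. The RNA pool as a random block was not run, since limma's duplicateCorrelation gave no estimate with 3 arrays. The GC correction was not run either, as the sources used here held the gene annotation but no genome sequence. The 19 gene lists had no rows to test. With 1 replicate left out no test was possible. Negative-control spots were 46.8, 45.4 and 31.1 times as bright as the local background in green on arrays 1, 2 and 3, so features near that level have little signal behind their ratios. With that level as the background 2699 features passed. The SorX ratio stayed at 2.00 and the size rule at 18, as normexp fits a level of its own and takes up a constant background. This setting therefore could not show how far that level affects the ratios.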

Other observations

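The permutation of the numbers was chosen after the result was seen. Features with consecutive numbers had similar log2 ratios. Over 4308 pairs the correlation of the slide mean between a feature and the next number was 0.319, and the highest of 10000 permutations of the numbers was 0.0518 (permutation p = 1e-04, the smallest they can give). Pairs whose spots all lay over 20 rows or columns apart correlated at 0.328 over 1687 pairs, which speaks against placement on the array as the source. The correlation between array 1 and array 3 of the next number, on different slides, was 0.201. A candidate explanation is that consecutive numbers follow gene order, so that neighbours share transcripts, but the files used here do not pair the numbers with genes. Among features past the slide test, there were 13 runs of at least 3 consecutive numbers with lower ratios, against at most 3 in 1000 permutations. There were 6 such runs with higher ratios, against at most 7.

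The median of the 23 antisense features, 0.16, lay at percentile 99.5 of 10000 random lists of numbered features matched on brightness, whose central 95% ran from -0.15 to 0.11. In camera the class had an adjusted p of 0.339 with an estimated correlation. With median centring its median was 0.04, at percentile 97.6 of matched lists (-0.24 to 0.04), and the adjusted p in camera was 0.225. With array 3 left out it was 0.15, at percentile 98.2 (-0.18 to 0.14), with an adjusted p in camera of 0.132 (limma). These percentiles describe these arrays only, and were computed after the data were seen. Several antisense features rest on 1 probe, such as asRSP3018_No1, while numbered features such as 640072129 average 3. Single probes can spread more than such averages, which a match on brightness does not address, so the percentiles may be too high. They do not separate the antisense class from the probe design set of its asRSP members.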
